A study of Mus musculus with 18 samples.

How the data were processed

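The series holds RNA-seq of 18 libraries from retinas of postnatal day 30 rd1 mice on the FVB background. Per the labels, mice received subretinal AAV8-GFP or AAV8-GFP together with AAV8-TGFB1, retinas were dissociated with papain, and microglia and non-microglia were separated by antibody staining and cell sorting into lysis buffer. Libraries of polyA RNA were made with a modified Smart-Seq2 protocol. Microglia form 7 GFP and 7 TGFB1 libraries, and non-microglia 2 GFP and 2 TGFB1 libraries.

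The authors deposited one table of raw read counts per Ensembl gene, with one column per library and no normalization. Per the submitters' processing notes, reads were aligned with STAR to GRCm38.p6 and assigned with featureCounts, and DESeq2 was used. Versions of these tools, the annotation release, the strand setting and read filters are not given in the sources used here. The table was checked to hold whole numbers with a different total in each column. It has 54532 genes, of which 54409 were matched by Ensembl identifier to a symbol and position in the GENCODE M21 annotation of GRCm38. The other 123 identifiers were tested by identifier only. Exon overlaps between genes were computed with bedtools 2.31.1, since reads in shared exons appear to be counted for both genes: AY036118, which lies wholly in Gm42418, has 1925252 counts against 2079650 (r = 0.9999 over the 18 libraries). Library totals and shares thus hold some reads more than once, and 2 overlapping genes can be called on the same reads. The exons of 1216 genes lie wholly in exons of other genes, and 659 of these have 10 or more counts. All 18 columns were used.

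Total counts per library ran from 1582451 to 3064027. Smart-Seq2 reads carry no molecular identifiers, so counting intervals (Poisson, 95%) and floors (3 counts per library) cover counting error only. The floor corresponds to 0.979 to 1.90 CPM, counts scaled to 1e+06 per library. The labels do not say whether libraries of a group come from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

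Groups were taken from the sample titles. Gene lists, comparisons, tests, the rule for named genes and all but 9 of the alternatives were fixed before the data were examined. Each comparison used edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr and the quasi-likelihood F test with robust dispersion, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. TGFB1 was compared with GFP in the microglia libraries alone and in the non-microglia libraries alone. The difference of these effects, and microglia against non-microglia in GFP retinas, came from one fit of all 18 libraries with 4 groups. CPM values use TMM-scaled library sizes of the fit they belong to and are given as mean ± SD.

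Fixed lists of genes for microglial states, pathways and cell types were tested where at least 3 members passed the filter: 24 lists in microglia, 30 in non-microglia and 33 in the fit of all libraries. The test was camera of limma 3.58.1 with a preset correlation between genes of 0.01, two-sided, adjusted over the lists tested. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. Summed CPM of each list per microglia library, as log2 after adding 1, were compared by a two-sided exact permutation test over all splits into 7 and 7 libraries, whose smallest possible p is 0.000583.

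Named genes are Tgfb1 and, in each treatment comparison, the 8 higher and 8 lower called genes with the smallest p, or all where fewer passed. Up to 4 called members of each list follow, or up to 2 members with the smallest p, given as not passing, where none passed. The rule takes up to 5 called genes per direction for the difference of effects, and marker list members only for microglia against non-microglia. Predicted genes and pseudogenes were counted but not named. Results of 2 genes are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

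Alternatives were DESeq2-type (RLE) size factors in edgeR, no filter on low counts, no robust dispersion, DESeq2 1.42.0, limma voom with quality weights, a block for the replicate number, and leaving out each library in turn. For microglia, covariates for RNA of other retinal cells, for Y chromosome genes and for library size were tried, and both treatment comparisons were also taken from the fit of all 18 libraries. The alternatives added after the counts were seen are the libraries with Xist counts only, those with Y counts only, leaving out the 3 libraries farthest apart on the principal components, a covariate for the share of 3 rRNA repeat genes, microglia without these genes, replicates 2 to 4 against 5 to 8 as a covariate, each of these parts alone, and leaving out hemoglobin, Tgfb1 and rRNA repeat genes.

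The models were tested on simulated counts with 200 changed genes, drawn from the means, totals and dispersions of these libraries. Changed genes were placed only among genes above a minimum mean count, so recovery at low counts is not shown. Of genes changed 1.5-fold, 2-fold and 4-fold, 50.7%, 92.5% and 95.5% were called in the microglia design, 34.3%, 74.6% and 100% in the non-microglia design, and 3.0%, 25.4% and 72.7% for the difference of effects. Unchanged genes called numbered 3, 15 and 6, among 10762, 13226 and 14892 genes tested. They are a larger share of the genes called than of those tested, and that share was highest in the non-microglia design. Among the genes called, it was under 0.05 in the microglia design. It was above 0.05, the threshold used, in the non-microglia design and for the difference of effects. Of 50 random lists of unchanged genes per treatment design, 0 and 1 had an unadjusted camera p under 0.05. Simulated genes were drawn independently of each other, so this cannot show how the preset correlation holds for correlated genes. To ask how often regrouping gives as many calls, 100 of the 1716 splits of the microglia libraries into 7 and 7 were drawn, the real one included. A median of 2 lists was called by camera over these 100 splits. Added after the data were seen, the 64 splits that part all equal replicate numbers and the 35 that keep them together were fitted as well. Tables and figures were made with pandas 2.3.3 in Python 3.11.15 and with the R package data.table, version 1.17.8. Whether members of a list changed by different amounts in non-microglia was asked with an exact permutation test over the 3 distinct splits of the 4 libraries, whose smallest possible p is 0.333. That test was added after the values were seen.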

Results

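The data are gene counts from microglia and from the other cells of the retina in rd1 mice, whose Pde6b mutation leads to the death of rods and then of cones. Retinas had received a virus for green fluorescent protein alone (AAV8-GFP) or together with a virus for transforming growth factor beta 1 (AAV8-TGFB1), a cytokine that microglia depend on for their resting identity. Microglia were measured in 7 GFP libraries, with 1766307 to 3064027 counts each, and 7 TGFB1 libraries, with 1582451 to 3044182. Non-microglia were measured in 2 GFP libraries, with 2318212 and 2604930 counts, and 2 TGFB1 libraries, with 2392931 and 2378669. Each library had a count in 19947 to 26333 genes. Between 8.86% and 18.3% of the counts fell in 3 rRNA repeat genes, or 6.41% to 13.7% without AY036118, whose reads are also counted for Gm42418. Xist RNA was found in 6 microglia libraries, replicates 2, 7 and 8 of each treatment, and Y chromosome genes in the other 12 libraries.

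The comparison of microglia between treatments asks whether TGFB1 delivered to the degenerating retina changes these cells. It found a small set of modest changes: of 10970 genes tested, 26 rose and 8 fell in TGFB1 retinas (edgeR quasi-likelihood, Benjamini-Hochberg), with a median absolute log2 fold change of 0.48 among the 34. Csf1, Lgals3, Clec7a and Axl, which are known from activated microglia, were among those that rose, as was H2-DMa of the MHC class II pathway. Gas6, which encodes a ligand of Axl, and Tgfbi, a matrix protein gene named for its induction by TGF-beta, were among those that fell. Tgfb1 itself was not called in microglia, at 13.5 ± 5.72 CPM (SD, n = 7) in TGFB1 retinas and 11.8 ± 2.46 in GFP retinas (log2 fold change 0.20, SE 0.22, edgeR adjusted p = 0.931).

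Ctsw, which encodes the cysteine protease cathepsin W (ENSMUSG00000024910, GRCm38 chromosome 19, 5465043 to 5468507), rose most, from 4.66 ± 1.90 to 18.9 ± 3.21 CPM (n = 7 each, log2 fold change 1.98, SE 0.23, edgeR adjusted p = 3.68e-05). Csf1, a growth factor for microglia and macrophages (chromosome 3, 107741048 to 107760469), rose from 19.7 ± 6.18 to 38.8 ± 10.1 CPM (log2 fold change 0.98, SE 0.19, edgeR adjusted p = 0.0206). Lgals3, which encodes the lectin galectin-3 (chromosome 14, 47367751 to 47386160), rose from 14.6 ± 4.75 to 31.2 ± 9.96 CPM (log2 fold change 1.07, SE 0.22, edgeR adjusted p = 0.0256). Clec7a, the gene of the beta-glucan receptor dectin-1, rose from 25.2 ± 6.73 to 45.2 ± 10.7 CPM (log2 fold change 0.83, SE 0.17, edgeR adjusted p = 0.0256); GENCODE lists it as a polymorphic pseudogene. H2-DMa, whose product loads peptides onto MHC class II (chromosome 17, 34119541 to 34139101), rose from 119 ± 9.60 to 159.9 ± 7.66 CPM (log2 fold change 0.43, SE 0.07, edgeR adjusted p = 0.00522). Smaller or similar rises were measured for Tnfsf13b, a B cell survival factor (0.41, adjusted p = 0.00599), Lhfpl2 (0.47), the actin-capping gene Capg (0.48), the sialomucin gene Cd34 (0.34), the mitochondrial folate enzyme gene Mthfd2 (0.65) and the sialic acid receptor gene Siglecf (0.50, adjusted p = 0.00840). Cd300lb, named after its values were seen, is the remaining gene with a change of at least 2-fold besides Ctsw, Lgals3 and Wfdc17 (log2 fold change 1.26, SE 0.27, edgeR adjusted p = 0.0256).

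Among genes that fell, Gas6 (chromosome 8, 13465374 to 13494490) went from 193 ± 27.7 to 128 ± 17.9 CPM (n = 7 each, log2 fold change -0.59, SE 0.10, edgeR adjusted p = 0.00599). Tgfbi (chromosome 13, 56609523 to 56639562) went from 82.5 ± 5.67 to 58.9 ± 2.88 CPM (log2 fold change -0.49, SE 0.08, edgeR adjusted p = 0.00599). Naaa, a lysosomal amidase gene, went from 171 ± 25.04 to 123 ± 10.2 CPM (-0.48, edgeR adjusted p = 0.00654), and Wfdc17 from 14.5 ± 4.14 to 7.17 ± 2.12 CPM (-1.04, edgeR adjusted p = 0.0434). The others were the membrane protein genes Tmem176b (-0.35) and Tmem176a (-0.32), the neonatal Fc receptor gene Fcgrt (-0.49) and Emp3 (-0.44). For each of the 21 genes named by the rule that passed, 7 of 7 TGFB1 libraries lay on that side of the GFP mean, which selection by the test favours. The groups did not overlap at all for 25 genes, where chance gives 0.0583% of genes or 6.39 in all, and 14 of the 25 were called.

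**Figure D1:**
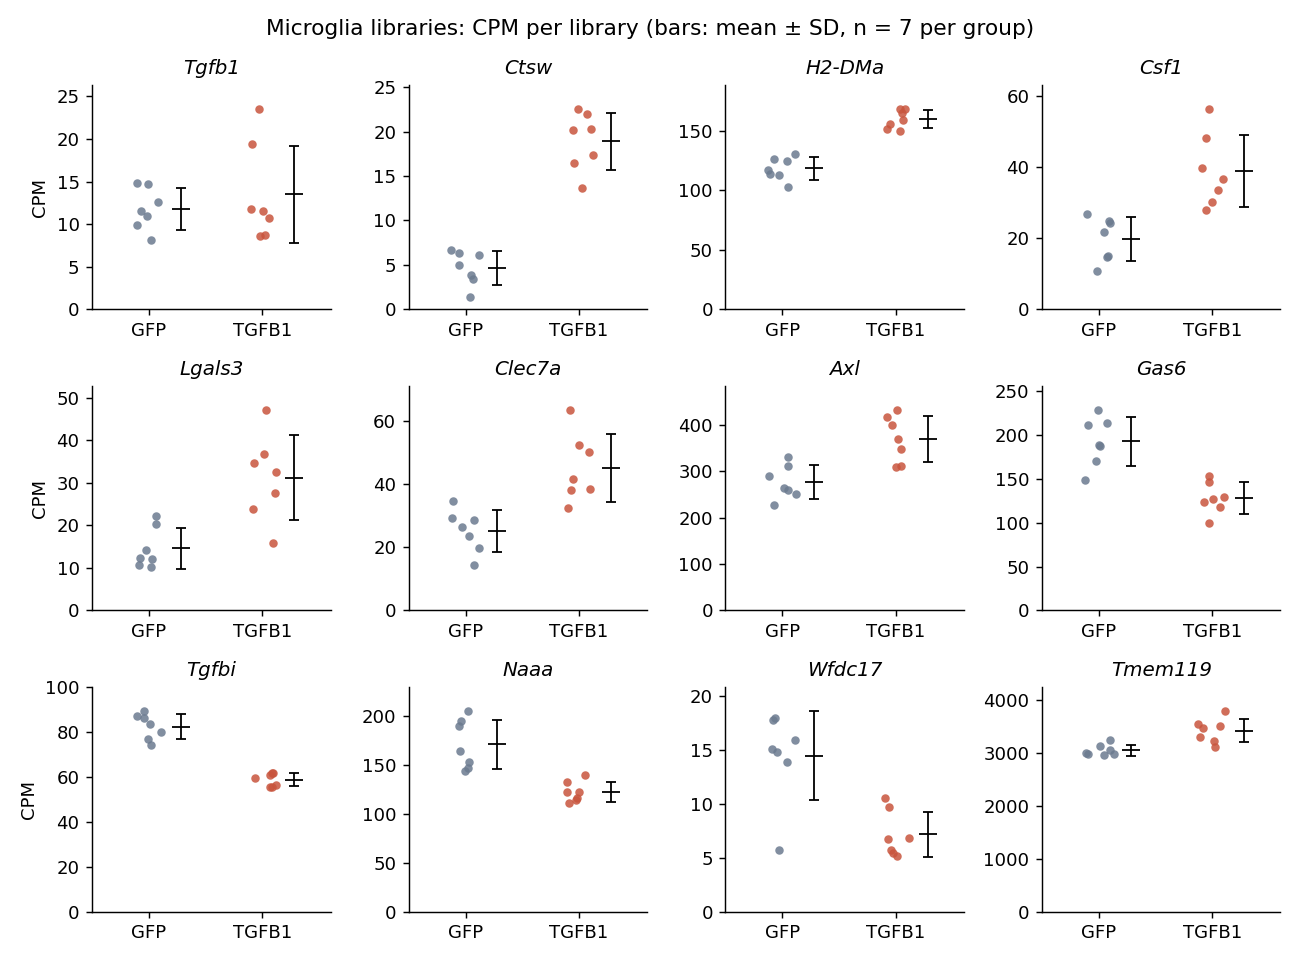
CPM of 12 genes in each microglia library (points) with the mean and SD of each treatment group (n = 7 each). Ctsw lies between 13.6 and 22.5 CPM in the TGFB1 libraries and between 1.37 and 6.64 in the GFP libraries, whereas Tgfb1 and Tmem119 overlap between the groups and were not called.

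Of the 24 fixed lists tested in microglia, 7 were higher in TGFB1 retinas and 2 lower than other genes by camera, and 1 call, MHC class II, held with an estimated correlation. In the disease-associated microglia list, 4 of 24 members rose (Csf1, Lgals3, Clec7a and Axl) and 20 did not pass, with 9 higher when adjusted over the list alone. Its median log2 fold change was 0.13 (camera adjusted p = 5.33e-10), and the adjusted p = 0.212 with an estimated correlation. Axl, a receptor for the uptake of dying cells, rose from 277 ± 36.3 to 369.9 ± 49.1 CPM (n = 7 each, log2 fold change 0.42, SE 0.09, edgeR adjusted p = 0.0335). In the MHC class II and co-stimulation list, H2-DMa rose and 7 of 8 members did not pass. All 8 had positive log2 fold changes, and 4 were higher when adjusted over the list alone (median 0.32, camera adjusted p = 1.66e-07). Its adjusted p = 0.0490 with an estimated correlation, and 0.0165 by fry. It was the 1 list of 24 that passed by fry for change in one direction. The disease-associated microglia list had a fry adjusted p = 0.199.

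In the list of TAM receptor and integrin genes of outer retina microglia, Axl and Lgals3 rose, Gas6 fell and 8 of 11 did not pass (median 0.12, camera adjusted p = 0.00264; adjusted p = 0.212 with an estimated correlation). Adjusted over the list alone, 4 were higher and 1 lower. In the lysosome list, Man2b1, a mannosidase gene, rose from 2089 ± 124 to 2442 ± 128 CPM (n = 7 each, log2 fold change 0.23, SE 0.05, edgeR adjusted p = 0.0438) and 24 of 25 did not pass, with 3 higher when adjusted over the list alone. The lysosome median was 0.06 (camera adjusted p = 0.00264), and the adjusted p = 0.460 with an estimated correlation. In 1 alternative, the libraries with Y counts only, the lysosome list turned downward without being called. None of the members of the remaining called lists passed singly. For inflammatory cytokines and chemokines (12 members, 1 higher when adjusted over the list alone), the median was 0.17 (camera adjusted p = 0.00144; adjusted p = 0.212 with an estimated correlation), with Ccl4 at 0.60 (adjusted p = 0.0710) and Ccl3 at 0.31 (0.688). For the type I interferon response (16 members, 15 positive, 0 when adjusted over the list alone), the median was 0.21 (camera adjusted p = 0.00155; adjusted p = 0.288 with an estimated correlation), with Oasl2 at 0.94 (SE 0.34, adjusted p = 0.517) and Ifi27l2a at 0.43 (0.411). For the cell cycle (20 members, 15 positive, 0 when adjusted over the list alone), the median was 0.08 (camera adjusted p = 0.0235; adjusted p = 0.506 with an estimated correlation).

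**Figure D2:**
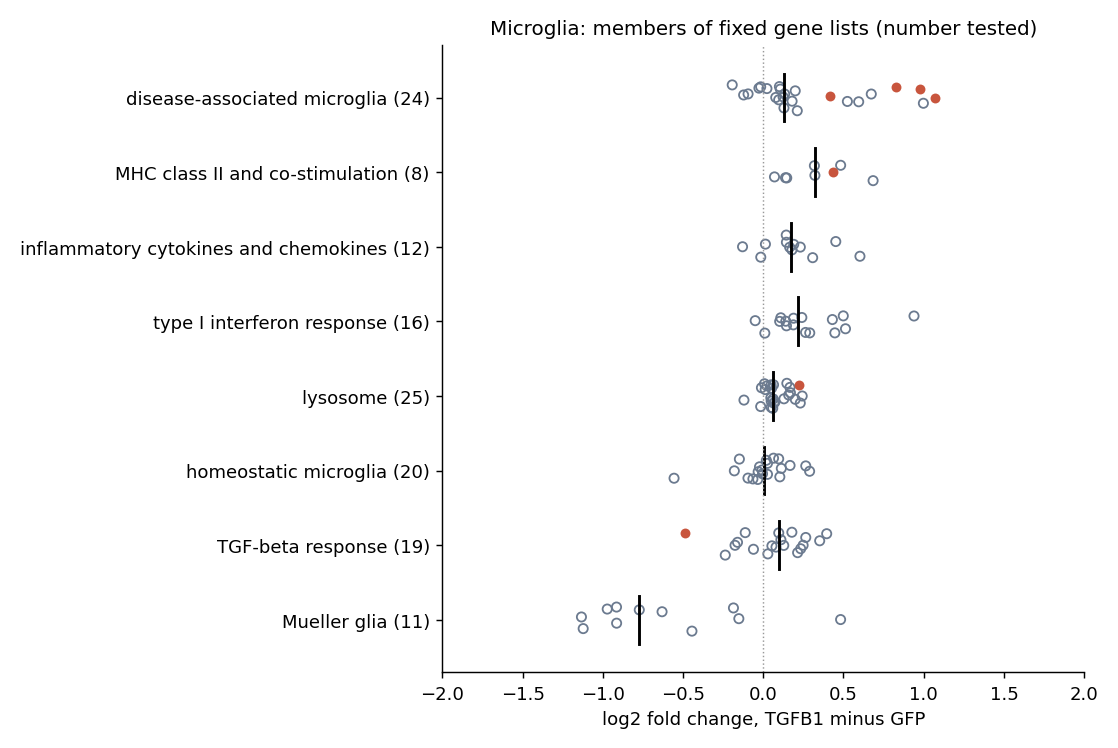
Log2 fold change (TGFB1 minus GFP) in microglia of the members of 8 fixed lists. Filled points passed over all genes tested, open points did not, and black bars are list medians, which lie between -0.77 for Mueller glia and 0.32 for MHC class II.

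The homeostatic microglia list was not called (median 0.01, camera adjusted p = 0.689): 0 of its 20 members passed over all genes, and 2 were higher and 2 lower when adjusted over the list alone. Its summed level was 68899 ± 5322 CPM in TGFB1 and 68270.0 ± 5540 in GFP retinas (n = 7 each), and fry for change in either direction gave an adjusted p = 0.00103. Its members Tmem119 (3425 ± 226 against 3051 ± 107 CPM, log2 fold change 0.17, edgeR adjusted p = 0.230) and the receptor gene Tgfbr1 (0.26, SE 0.07, edgeR adjusted p = 0.142) did not pass. In the TGF-beta response list, Tgfbi fell and 18 of 19 members did not pass (median 0.10, camera adjusted p = 0.664), with Tgfbr1 higher and Tgfbi lower when adjusted over the list alone. The phagocytic receptor list held the Axl rise and the Gas6 fall and was not called (camera adjusted p = 0.608). The complement list was not called (adjusted p = 0.936). Its median of -0.05, its mean of 0.07 and the downward direction of the test differed in sign. The glycolysis list (adjusted p = 0.997) differed likewise, with a median of -0.01 and an upward test. Change in either direction was not particular to the homeostatic list. Fry for it gave an adjusted p = 0.000428 for the TGF-beta response, 0.000348 for phagocytic receptors and 0.0106 for complement, but 0.264 for glycolysis. Across the 15 lists not called in microglia, camera adjusted p ran from 0.0566, for MHC class I presentation, to 0.997.

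Of 5 lists of other retinal cells tested in microglia, 2 were called and neither had a member that passed. The Mueller glia list was lower in TGFB1 microglia (11 members, 1 positive, median -0.77, camera adjusted p = 0.00790; adjusted p = 0.506 with an estimated correlation), as were 3 retinal ganglion cell genes (median -0.50, camera adjusted p = 0.0371; adjusted p = 0.360 with an estimated correlation). Cone (camera adjusted p = 0.487), bipolar (0.563) and pigment epithelium genes (0.487, 3 of 3 positive) were not called. The ganglion cell genes were not lower in microglia than in non-microglia of GFP retinas. No member of either list passed singly or when adjusted over the list alone, with Rlbp1 at -1.13 (SE 0.65, adjusted p = 0.843) and Nefl at -0.50 (0.811). The summed Mueller glia level was 433 ± 183 CPM in TGFB1 and 591 ± 263 in GFP microglia (n = 7 each, two-sided exact permutation p = 0.170, adjusted p = 0.477), against 25489 ± 695 in GFP non-microglia. GFP replicates 2 and 5 had the highest Mueller glia levels, 968 and 965 CPM, with the other GFP libraries at 369 to 552. TGFB1 replicate 6 was at 821 CPM and the other TGFB1 libraries at 269.5 to 486. The lower mean in TGFB1 microglia thus rests largely on few libraries. The rRNA repeat genes took 8.86% to 16.3% of counts in TGFB1 and 13.5% to 18.3% in GFP microglia. By summed level per library, 0 lists passed in microglia: 5 had an unadjusted exact permutation p under 0.05, and the smallest adjusted p was 0.258. The inflammatory list was at 787 ± 71.8 against 679 ± 49.2 CPM (exact p = 0.00991) and the MHC class II list at 866 ± 123 against 707 ± 93.7 (exact p = 0.0134).

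Single libraries moved the counts: 17 genes rose without TGFB1 replicate 3, 14 without GFP replicate 3, 16 without GFP replicate 4, 14 without TGFB1 replicate 7 and 10 without TGFB1 replicate 8. Without GFP replicate 2, 14 genes fell and 5 lists were called, and 5 genes fell without GFP replicate 3. Of the 34 genes, 15 to 30 were still called without any 1 library, and 0 changed sign. Leaving out 1 library ended no call among Ctsw, H2-DMa, Tgfbi, Gas6, Tnfsf13b, Lhfpl2, Capg, Tmem176b, Naaa, Cd34, Mthfd2, Fcgrt and Siglecf. It ended those of Tmem176a in 2 of the 14 fits (largest adjusted p = 0.0556, without GFP 3), Csf1 in 4 (0.0755, GFP 3), Clec7a in 6 (0.0933, TGFB1 8), Emp3 in 8 (0.0875, TGFB1 8), Lgals3 in 10 (0.0871, GFP 3), Axl in 10 (0.112, GFP 3), Wfdc17 in 11 (0.143, GFP 7) and Man2b1 in 11 (0.122, TGFB1 4), and that of Cd300lb in 6 (0.0995, TGFB1 7). In the fit of all 18 libraries the calls of Tgfbi, Cd34, Tmem176a, Emp3, Clec7a, Axl, Wfdc17 and Man2b1 ended. Of the 14 fits, the lysosome list was still called in 13 (largest adjusted p = 0.102, without GFP 2), cell cycle in 8 (0.279, TGFB1 7), Mueller glia in 12 (0.182, GFP 2) and ganglion cells in 10 (0.182, GFP 2). Libraries of replicates 2, 3 and 4 differed from replicates 5 to 8 in 257 autosomal genes, a grouping chosen after the values were seen. With this grouping as a covariate 27 genes rose and 10 fell with TGFB1, with the fewer libraries of replicates 2 to 4 alone it was 3 and 1, and with 5 to 8 alone 4 and 0 (edgeR, 238 lower at unadjusted p under 0.05).

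The same comparison in the cells left after microglia were sorted out asks how the rest of the retina differed. Tgfb1 transcripts were found in the TGFB1 libraries of this fraction, bipolar cell genes were higher, and hemoglobin genes were lower. Tgfb1 (ENSMUSG00000002603, GRCm38 chromosome 7, 25687002 to 25705077) had 462 and 402 counts in the TGFB1 libraries, 197 CPM (95% Poisson interval 179.8 to 216) and 171 CPM (155 to 188), and 0 counts in both GFP libraries, whose floors are 1.14 and 1.32 CPM. It was at least 139-fold higher (edgeR adjusted p = 3.71e-15). The labels do not say whether the virus carries the mouse or the human sequence, so these are reads assigned to the mouse gene, whether from the genome or the vector. Of 13598 genes tested, 46 rose and 7 fell (edgeR quasi-likelihood, Benjamini-Hochberg), with a median absolute log2 fold change of 0.74 and 13 of at least 2-fold. Of these 53 genes, 5 share at least 50% of their exon bases with other genes, so some calls may rest on the same reads. In simulated counts of this design, false calls were a larger share of the genes called than the threshold of 0.05 aims at.

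Bipolar cells relay photoreceptor signals to the inner retina. In their list, 8 of 10 members rose and 2 did not pass, with 9 higher and 1 lower when adjusted over the list alone (median 0.76, camera adjusted p = 9.24e-32; adjusted p = 0.584 with an estimated correlation). Trpm1, the light-response channel gene of ON bipolar cells (chromosome 7, 64153835 to 64269775), rose from 464 ± 29.1 to 871 ± 117 CPM (n = 2 each, log2 fold change 0.91, SE 0.09, edgeR adjusted p = 4.92e-06). Grm6, the glutamate receptor gene of the same cells, rose from 159 ± 7.64 to 299 ± 45.1 CPM (0.91, SE 0.11, edgeR adjusted p = 5.71e-05). Pcp2 (0.77, edgeR adjusted p = 0.000155) and Gng13 (1.02, edgeR adjusted p = 0.000331) rose as well, but share 51.5% of their exon bases with Pet100 (0.75, adjusted p = 0.000253) and 51.6% with Chtf18, so their counts cannot be assigned to one gene with certainty. Named after their values were seen, Cabp5 (0.74), Isl1 (0.72), Gabrr1 (0.78) and Prkca (0.66) rose too. In contrast, Grik1, a receptor gene of OFF bipolar cells, was at -0.41 (SE 0.17, adjusted p = 0.561). The summed list was at 3094 ± 296 CPM in TGFB1 and 1946 ± 62.8 in GFP libraries (n = 2 each). Outside the list, the secretory granule genes Scg2 (145 ± 20.9 to 322 ± 40.7 CPM, log2 fold change 1.15, edgeR adjusted p = 4.92e-06) and Chgb (0.83, edgeR adjusted p = 0.000155) rose.

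Hemoglobin genes fell together. Hbb-bs went from 561 ± 34.1 to 229 ± 9.91 CPM (n = 2 each, log2 fold change -1.30, SE 0.09, edgeR adjusted p = 3.18e-09), Hba-a1 from 304 ± 27.0 to 113 ± 1.38 CPM (-1.43, edgeR adjusted p = 1.04e-08) and Hbb-bt from 35.4 ± 3.87 to 11.9 ± 2.46 CPM (-1.57, edgeR adjusted p = 0.00540). In the erythroid list 3 of 4 members fell, and 4 when adjusted over the list alone (median -1.36, camera adjusted p = 5.26e-37; adjusted p = 0.484 with an estimated correlation). The other genes that fell were Enpp2 (-0.54, adjusted p = 0.0161), which makes lysophosphatidic acid, Mir99ahg (-0.51), Adam11 (-0.67) and the immediate early gene Jun (-0.48, adjusted p = 0.0386). For every named gene that passed, both TGFB1 libraries lay on that side of the GFP mean, which selection by the test favours.

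Photoreceptor and Mueller glia lists were lower without any member passing singly. The rod list (8 members, 1 lower when adjusted over the list alone) had a median of -0.40 (camera adjusted p = 0.00141; adjusted p = 0.932 with an estimated correlation) and 618 ± 68.2 against 836 ± 149 CPM (n = 2 each), with the arrestin gene Sag at -0.83 (SE 0.16, adjusted p = 0.0799). The cone list (11 members, 1 higher and 4 lower when adjusted over the list alone) had a median of -0.32 (camera adjusted p = 0.00716; adjusted p = 0.932 with an estimated correlation) and 2449 ± 387 against 3215 ± 374 CPM, with Gnb3 at 0.36 (adjusted p = 0.0528) and Pde6h at -0.55 (0.119). The Mueller glia list (12 members, 1 higher and 2 lower when adjusted over the list alone) had a median of -0.12 (camera adjusted p = 0.0494; adjusted p = 0.888 with an estimated correlation) and 23605 ± 437 against 25489 ± 695 CPM. The TGF-beta response list, with 0 of 21 members passing, was not called (median -0.06, camera adjusted p = 0.332), with Id2 at -0.35 (adjusted p = 0.355) and Id1 at -0.38 (0.663). Across the 25 of 30 lists not called, camera adjusted p ran from 0.0650, for immediate early and stress genes, to 0.961. By fry for change in one direction, 0 of the 30 lists passed, bipolar and erythroid genes included. Median, mean and test differed in sign for complement (median 0.09, mean -0.20, test down), cell cycle (-0.08, -0.05, up), glycolysis (0.02, -0.01, up), TAM and integrin genes (0.02, 0.12, down), amacrine cells (-0.15, 0.07, down), pigment epithelium (0.07, 0.13, down) and Y genes (-0.02, 0.01, down).

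**Figure D3:**
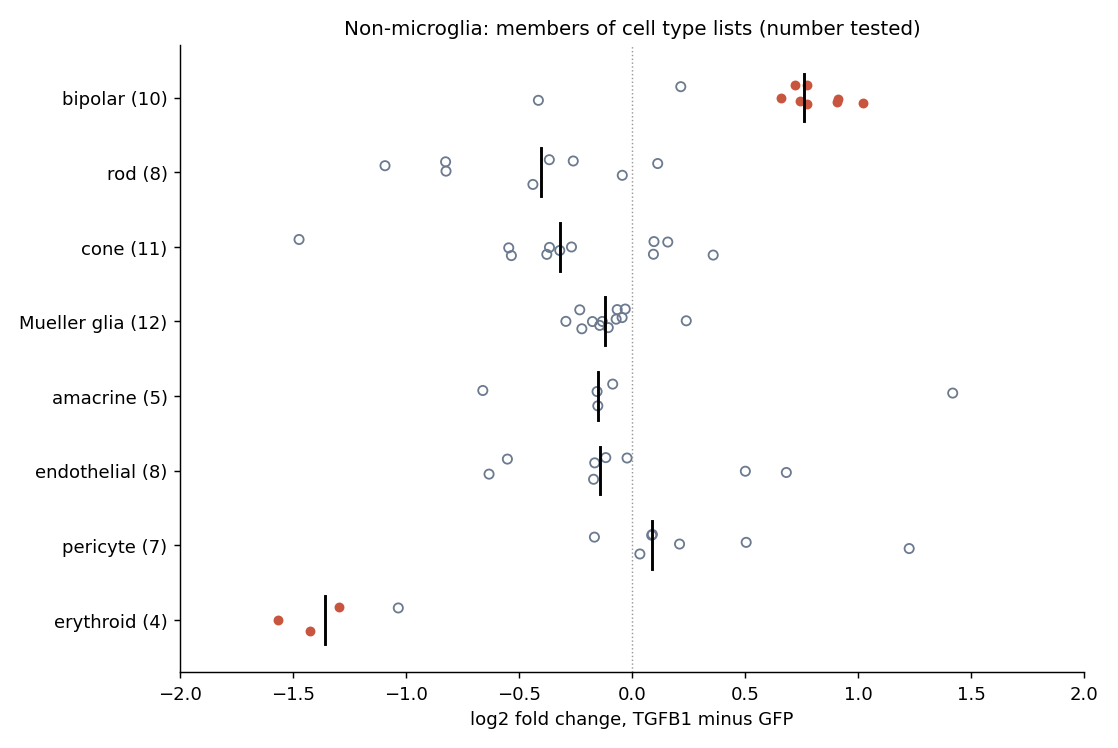
Log2 fold change (TGFB1 minus GFP) in non-microglia of the members of 8 marker lists. Filled points passed over all genes tested and open points did not. Black bars are list medians, 0.76 for bipolar cells and -1.36 for erythroid genes.

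With 2 libraries per group, the test rests on the spread shared across genes: 22 genes rose without TGFB1 replicate 1, 87 without GFP replicate 1 and 77 without GFP replicate 2. Moreover, 23 and 33 fell without GFP replicates 1 and 2, and 3 lists were called without GFP replicate 2. In the fit of all 18 libraries, 4 genes rose and 0 fell (500 of 15321 at unadjusted p under 0.05 by edgeR). That fit ended the calls of Trpm1, Grm6, Pcp2, Pet100, Gng13, Scg2, Chgb, Hbb-bs, Hba-a1, Hbb-bt, Enpp2, Mir99ahg, Adam11 and Jun, with log2 fold changes near those above, such as 0.90 for Trpm1 and -1.30 for Hbb-bs. Of the 53 genes, 23 to 49 were still called without any 1 library and 0 changed sign. Calls ended for Hbb-bt in 1 of the 4 fits (largest adjusted p = 0.0618, without TGFB1 2), Gabrr1 in 1 (0.188), Enpp2 in 2 (0.264, TGFB1 1), Prkca in 2 (0.585), Mir99ahg in 3 (0.243, TGFB1 1), Jun in 3 (0.396, TGFB1 1) and Adam11 in 4 (0.233, TGFB1 2). The rod list was still called in 2 of the 4 fits (largest adjusted p = 0.534), the cone list in 3 (0.8865) and the Mueller glia list in 1 (0.307), with the largest value without GFP 2 each time.

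Whether the effect of TGFB1 differed between the fractions was tested directly, and 2 of 15321 genes did so. Tgfb1 was called (edgeR adjusted p = 1.55e-08), with the lower effect in microglia. Reads assigned to it may come from the vector, so this call cannot show a response of the mouse gene. By edgeR quasi-likelihood and by DESeq2, 0 genes were called with a higher effect in microglia. Limma voom called 1, and edgeR with no filter on low counts 3. In edgeR, 711 genes had an unadjusted p under 0.05. Few differences could have been called: in simulated counts 3.0% of 1.5-fold and 25.4% of 2-fold differences were recovered. Of 33 lists, 0 were called by camera, 5 had an unadjusted p under 0.05, and 0 were called with an estimated correlation. Among the 9903 genes tested in both fractions, 16 were higher in microglia and 22 in non-microglia, 5 and 3 were lower. In either direction 0 were shared, where chance gives 0.0355 and 0.00151. With so few expected, a count of 0 cannot show whether the fractions respond differently.

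Microglia against non-microglia in GFP retinas shows what the sort separated. Homeostatic microglia genes were higher in the sorted fraction, and Mueller glia, bipolar and rod genes in the rest. Of 15321 genes, 4585 were higher and 5245 lower in microglia (edgeR quasi-likelihood), 7417 of them by at least 2-fold. All 20 homeostatic microglia genes were higher (median 8.41, or 8.27 with genes at 0 counts at their bound, camera adjusted p = 3.84e-57; adjusted p = 4.52e-05 with an estimated correlation). Csf1r, the receptor for Csf1, was at 10995 ± 454 CPM in microglia (n = 7) and 9.10 ± 0.00947 in non-microglia (n = 2). C1qa was at least 4100.4-fold, Trem2 at least 1054-fold and Itgb2 at least 914-fold higher in microglia. Of 25 lysosome genes, 23 were higher (median 3.33, camera adjusted p = 1.65e-30; adjusted p = 0.00669 with an estimated correlation). All 12 Mueller glia genes (median -5.68), 10 of 10 bipolar genes (-4.34), 8 of 8 rod genes (-5.87) and 4 of 4 erythroid genes (-8.08) were lower in microglia. In contrast, 3 of 4 retinal ganglion cell genes were higher in microglia and 0 lower (median 1.63), and that list was not called (camera adjusted p = 0.521). By camera the Mueller glia list (adjusted p = 3.21e-05; adjusted p = 0.272 with an estimated correlation), the rod list (0.00304; adjusted p = 0.170 with an estimated correlation) and the erythroid list (0.0435; adjusted p = 0.272 with an estimated correlation) were called. In all, 15 of 33 lists were called, 7 of them with an estimated correlation.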

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

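Of the tests in this part, those for a larger share of bipolar cells, for fewer red blood cells, for the share of rRNA repeat counts and for splits that part equal replicate numbers were chosen after the results were seen.

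The set of 34 genes and 9 lists that differed between TGFB1 and GFP microglia was weighed first. In 100 splits of the 14 libraries into 7 and 7, only the real one, 1 of 100, called at least 34 genes (highest other 15). Chance can thus be excluded for the number of genes, at a limit of 5 of 100 splits. For the lists, 4 of 100 splits called at least 9 (real 9, highest other 12). That is under the limit, but other groupings reached or passed the real number, so chance is not firmly excluded for it. In the 64 splits that part all equal replicate numbers, 1 called at least as many genes (highest other 18) and 3 as many lists (highest other 9). Taken singly, MHC class II (1 of 100 splits with as small a p) and disease-associated microglia (4) fell under 5. For the latter, another split gave a smaller camera p (2.43e-12 against 2.22e-11), and both were picked from 9 called lists. Chance is not excluded for the other lists: TAM and integrin genes 6, inflammatory 7, ganglion cell 13, interferon 15, lysosome 19, and cell cycle and Mueller glia 29 each. RNA of other retinal cells is argued against as the whole cause. Its lower level in TGFB1 microglia is itself uncertain (Mueller glia exact permutation p = 0.170). With its level as a covariate, the log2 fold changes of the 34 genes kept a median of 0.932 of their size (quartiles 0.859 to 1.01). The Mueller glia list went from -0.77 to 0.07 in that fit. This follows from the list being part of the covariate and is no evidence. Cone genes, also part of the covariate, were in GFP microglia at 9.33% of their GFP non-microglia level. The other lists in it ran from 1.55% (rod) to 3.89% (amacrine). Some of the covariate may thus not be RNA of other cells, which limits what the kept fold changes can show. Of the 34 calls 13 remained, the median absolute log2 fold change went from 0.48 to 0.44 and standard errors grew 1.09-fold. The share of rRNA repeat counts gave 0.921 (quartiles 0.836 to 1.04) with 21 calls left and a median of 0.43, and is argued against likewise. An action of TGFB1 on microglia may explain the genes, and a different mix of microglial states, or a response to the second virus that TGFB1 retinas alone received, stays open and untested.

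The higher bipolar cell genes in non-microglia of TGFB1 retinas were weighed next. Reads counted for overlapping genes are argued against, since 1 of the 10 genes, Gng13, has at least 50% of its exon bases in a gene with more counts. A larger share of all bipolar cells would raise the 10 genes by one amount, and their log2 fold changes ran from -0.41 (Grik1) to 1.02. The spread of these differences had an exact permutation p = 0.333, the smallest that 3 splits of the 4 libraries can give (real spread 1.61, highest other 0.0684), so this explanation is not excluded and stays open. A shift toward ON bipolar cells, or a change of their expression, could account for the pattern as well and was not tested.

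The lower hemoglobin genes in the same libraries were weighed last. Fewer red blood cells in the TGFB1 preparations would lower all 4 genes by one amount, and their log2 fold changes ran from -1.57 to -1.03. The exact permutation p of their spread was 1, but 3 splits of the 4 libraries cannot give a p below 0.333, so the test could not have spoken against this explanation, and fewer red blood cells may or may not be the source. No biological explanation was tested.

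The effect of TGFB1 on the reads assigned to Tgfb1 differed between microglia and non-microglia (edgeR adjusted p = 1.55e-08).

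Single libraries lay far from the other 6 of their group in 23 of 162 groups of values tested. The limit used flags about 1 in 20 groups that are separate and normally spread. These values were not log-transformed, and list sums were tested beside their own members, so 23 cannot be read as an excess over chance. Most of the flagged values are in microglia GFP replicate 2 and TGFB1 replicate 6. GFP replicate 2 had the lowest summed CPM for the homeostatic list (56889, others 66494 to 73618), the phagocytic receptor list (5865, others 6666 to 7095) and the glycolysis list (2058, others 2247 to 2322). It also had the lowest CPM of Atp5b (458, others 515 to 558), C1qb (3037, others 3568 to 3743) and Wfdc17 (5.72, others 13.9 to 18.01), and the highest of the bipolar list (236, others 15.2 to 74.1) and Trpm1 (60.7, others 0.738 to 16.6). TGFB1 replicate 6 had the highest mitochondrial share (3.41%, others 2.21% to 2.72%), Mueller glia list (821 CPM, others 269.5 to 486) and bipolar list (129 CPM, others 11.5 to 53.5). Its CPM were also highest for Car14 (20.4, others 2.56 to 8.63), Gfap (26.6, others 1.92 to 8.26), Grm6 (17.7, others 0 to 5.71), Rlbp1 (75.6, others 6.65 to 22.5), Trpm1 (19.8, others 1.44 to 8.40) and Vim (80.4, others 21.0 to 40.3). GFP replicate 3 had the highest complement list (14024 CPM, others 10789 to 12119). GFP replicate 5 had the lowest TGF-beta response list (2777 CPM, others 3239 to 3482). GFP replicate 6 had the highest cone list (389 CPM, others 275 to 298), and GFP replicate 8 the highest Lpl (57.6 CPM, others 22.5 to 36.7). TGFB1 replicate 7 had the highest MHC class II list (1113 CPM, others 739 to 894), and TGFB1 replicate 8 the highest Atf3 (95.5 CPM, others 47.7 to 60.6).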

How the results depend on the processing

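The alternatives with Xist or Y libraries only, by replicates 2 to 4 and 5 to 8, without 3 libraries, with the rRNA repeat share and without rRNA repeat or hemoglobin genes were tests chosen after the data were seen. In microglia, 26 genes rose and 8 fell. RLE size factors gave the same 26 and 8, limma voom 18 and 7, robust=FALSE 23 and 7, and leaving out the rRNA repeat genes 28 and 9. The rise count was 43 with DESeq2, 41 with the replicate block, 7 with the covariate for RNA of other retinal cells, 15 with that for rRNA repeat genes, 11 with all 18 libraries, 17 with Xist and 1 with Y libraries, 3 with replicates 2 to 4 and 4 with 5 to 8. The fall count was 25 with no filter, 14 with DESeq2, 19 with the replicate block, 16 with the Y covariate, 13 with library size, 4 with all 18 libraries, 2 with Xist, 2 with Y libraries, 1 with replicates 2 to 4, 0 with 5 to 8 (edgeR, 238 at unadjusted p under 0.05), and 18 without the 3 libraries farthest on the principal components (GFP 2, GFP 5 and TGFB1 6). Leave-one-out counts were 10 to 26 and 5 to 14. The reported fit called 9 lists by camera, and fry called 1. The camera count was 14 with no filter, 1 with an estimated correlation, 4 with Y libraries, and 5 to 11 leave-one-out. The lysosome list turned downward with Y libraries only (camera adjusted p = 0.937), and the cell cycle list with replicates 2 to 4 only (0.723). By list level, 0 passed in each alternative.

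In non-microglia, 46 rose and 7 fell. RLE gave 46 and 7, voom 43 and 7, and robust=FALSE 36 and 5. With no filter 86 rose and 16 fell, with DESeq2 30 and 4, with the replicate block 89 and 20, with all 18 libraries 4 and 0, and without hemoglobin, Tgfb1 and rRNA repeat genes 4 fell, the 3 hemoglobin genes having been removed. Leave-one-out counts were 22 to 87 and 6 to 33, with the lone library of a group assumed to vary like the others. The reported fit called 5 lists, and the count was 0 with an estimated correlation and 3 to 7 leave-one-out. For the difference of effects (0 higher, 2 lower), no filter gave 3 and 9, voom 1 higher, and robust=FALSE and the replicate block 1 lower. Leave-one-out counts were 0 to 1 and 1 to 2. Microglia against non-microglia gave 3944 to 4777 higher and 4368 to 5344 lower leave-one-out. Except where fewer samples or genes entered, the cause was not tested.

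Whether equal replicate numbers pair the libraries is undecided: 5 of 7 microglia pairs had r over 0.1 (-0.12 to 0.22), but 3 of 14 libraries matched best with their own number, and r was -0.07 in non-microglia. Xist or Y counts were of one kind in 7 of 7 pairs, a hint that equal numbers share an origin, and replicates 2, 3 and 4 differed as a group from the rest in 257 autosomal genes, which does not tie single numbers. Of named genes, the fit and the alternative gave the same call in 1569 cases in microglia, 172 calls were lost and 21 gained. In non-microglia these were 697, 37 and 27. The agreeing cases include named genes called in neither fit. Calls can be lost only among the 21 named genes called in microglia and the 16 in non-microglia. Leaving out 1 microglia library ended 1 to 8 of those 21 calls. Depth limits genes under 0.979 to 1.90 CPM, the floor of 3 counts.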

Other observations

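The tests of Xist against Y libraries below, the splits by replicate number and the choice of genes were made after the data were seen. Genes of the TGF-beta system differed between the fractions in GFP retinas, with ligand and receptor genes on both sides. Higher in microglia were Tgfbr1, at 418 ± 50.7 CPM (SD, n = 7) against 18.1 ± 1.80 (n = 2) in non-microglia (log2 fold change 4.52, edgeR adjusted p = 1.24e-17), Tgfbr2, at 519 ± 202 and 7.92 ± 5.005, and Nrros, which tethers latent TGF-beta on microglia, at 203 ± 21.6 CPM, with 1 count over both non-microglia libraries. Tgfb1 was at 12.6 ± 2.56 CPM in microglia and had 0 counts in non-microglia (edgeR adjusted p = 5.09e-08). Eng (3.45), Acvrl1 (2.90), Smad2 (0.92) and Smad3 (1.13) were also higher in microglia. Lower in microglia were Tgfb2, at 6.20 ± 6.48 against 269.7 ± 0.511 CPM (-5.54, edgeR adjusted p = 1.27e-08), Tgfb3 (-3.58), the receptor gene Tgfbr3 (-3.97), the latent TGF-beta binding gene Ltbp1 (-3.99) and the activating integrin gene Itgb8 (-3.86). Smad4 was not called (adjusted p = 0.218).

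Microglia libraries with Xist counts differed from those with Y counts in more than sex chromosome genes. Of 11204 genes, 41 were higher and 68 lower with Xist (edgeR quasi-likelihood with treatment in the model), 17 of them on X or Y and 92 autosomal. Nfkbia, an inhibitor of NF-kappaB, was lower (log2 fold change -0.96, SE 0.09, edgeR adjusted p = 8.21e-08), with Rgs1 (-0.74) and Tagap (-0.75). Tnf (0.77, SE 0.15, edgeR adjusted p = 0.00875), Fosb (1.83), Bhlhe40 (1.02) and Itgax (0.35) were higher. In 100 splits into 6 and 8 libraries, 1 of 100, the real one, gave at least 92 autosomal genes (highest other 3), so chance can be excluded for libraries regrouped singly. The Xist libraries are replicates 2, 7 and 8 of both treatments, and of the 35 splits that keep equal replicate numbers together 2 gave at least 92 autosomal genes, with 257 for replicates 2, 3 and 4 against the rest. The libraries thus carry a structure by groups of replicate numbers, and sex of the animals or a difference between replicate numbers, such as handling, may be the source of the 92. A test of the sex by treatment interaction called 0 of 12179 genes (edgeR; 588 at unadjusted p under 0.05).

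In non-microglia, Serpine3, named after its values were seen, had 95 and 53 counts in the TGFB1 and 11 and 1 in the GFP libraries (edgeR adjusted p = 0.00436). The size of the change is not settled, since the log2 fold change was 2.90 without GFP 2 and the GFP group is left with 1 count without GFP 1. The largest adjusted p of the leave-one-out fits was 0.00594, and 24.8% of its exon bases lie in Ints6.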
